A study of Mus musculus with 9 samples.

How the data were processed

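Thymic epithelial cells were sorted from enzymatically dissociated thymi into lysis buffer, and 3′-end RNA libraries were made by the MARS-seq protocol, per the labels' protocols. Groups were taken from the sample titles: 5 libraries of the group given 1 µg rAREG and 4 of the vehicle group, both 10 days after injection. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.5.2b, HTSeq, DESeq2 and the genome build mm10, with no roles or order. Strand use and the handling of reads that match several genes are not given in the sources used here.

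The deposited table held raw UMI counts per gene and library, and these counts were the basis of every test. The authors also deposited normalised values, a signal obtained by dividing the counts by size factors of 0.824 to 1.15; multiplied back, 100% of these values were whole within 1e-06 counts and equal to the raw counts, so no second fit was needed. Regularised log2 values and the authors' log2 fold changes of PBS over AREG, with their p-values and adjusted p-values, were in the same deposited table. Of the authors' own fit, counts of genes and their overlap with the present calls are given, and no test here rests on it. Of these 168 genes, 85 were higher in AREG and 83 lower, and 29 were marked as passing, each with an absolute log2 fold change of at least 1.01. Each of the 15080 genes reached at least 6 counts in some library, so the table had been filtered before deposit. It held no mitochondrially encoded gene among those analysed here.

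Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr by group, robust quasi-likelihood F test), and p was adjusted by the Benjamini-Hochberg method over 11636 genes; 3444 genes were left out by the filter. Genes with an adjusted p under 0.05 are said to have risen or fallen. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use TMM-scaled library sizes, and list scores are means of log2 CPM with a prior count of 2. The biological coefficient of variation was 0.148, and 3 counts, the limit a count of 0 allows, equal 1.39 to 1.94 CPM across the libraries; such limits cover counting error only. Lists with at least 5 tested genes were tested by fry (limma 3.58.1), which asks whether the genes of a list move, on balance, one way; its mixed test asks for change in either direction. By the mixed test 6 lists passed, the 3 that moved one way and the thymopoietic, type 2 and neuroendocrine lists. Camera, a separate limma test that compares a list with all other genes tested, called 9 lists with a preset correlation of 0.01. With a correlation estimated from the data it called none. Library measures and list scores were compared by two-sided exact permutation tests over 126 splits.

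Before the data were examined, the design, 28 lists and the rule for named genes were fixed. The rule took the 10 genes with the smallest adjusted p in each direction with a mean of at least 10 CPM in the higher group, leaving out predicted and pseudogene symbols. From each list it took up to 3 genes that passed over the list alone or else the most abundant one. Areg, Egfr, Foxn1, Psmb11, Aire, Ccl21a, Trpm5 and Mki67 were always taken where measured. A further 19 genes and 10 lists were chosen after seeing the data; these lists were tested as their own family. Positions come from GENCODE M21 on GRCm38, the build called mm10 in the processing notes; 11460 of 11636 tested symbols and all 81 named genes matched 1 annotated gene. Near-identical genes such as Ifit3 and Ifit3b, Iigp1 and Gm4841, or Hspa1a and Hspa1b, are uncertain as single genes.

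The fitting functions were tested on counts simulated from the real means, library sizes and dispersions, with 200 genes changed. In the simulated comparison of rAREG with vehicle, over 11393 genes, edgeR recovered 14.5% of 1.5-fold, 83.3% of 2-fold and 95.3% of 3-fold changes. False calls made up 7.59% of all calls, and fry called the 1 raised list and 0 of 20 unchanged lists. Most changes near 1.5-fold are thus missed at this depth and number of libraries. The simulated genes were drawn independently, whereas real list genes were correlated (estimated at 0.17 for the interferon list). The simulation therefore does not show how often fry calls unchanged lists of correlated genes. Chi-square statistics between pairs of libraries were at least 2.54 per degree of freedom, so no library repeated another within counting noise.

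The alternatives were DESeq2 1.42.0, RLE, upper-quartile or total-count scaling, no filter, a filter of 10 counts in 4 libraries, limma voom with sample weights, replicate numbers as a block, covariates for thymocyte genes and library size, other list tests, and leaving out each library. Covariates for a dissociation score and for a TEC mix score, the Aire-stage score minus the CCL21 and keratin 5/14 score, were added after seeing the data. Tables and figures were made with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.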

Results

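Gene expression was measured in thymic epithelial cells (TEC), the stromal cells that nurse and select developing T cells, sorted from the thymus of male wild-type mice. Recombinant amphiregulin (rAREG), a ligand of the EGF receptor, or its PBS vehicle had been injected into the thymus at 1 µg, 10 days before collection. The rAREG group held 5 libraries and the vehicle group 4, made by bulk MARS-seq, a 3′-end method that counts RNA molecules by unique molecular identifiers (UMIs). The libraries held 1523246 to 2159115 UMI counts over 15080 genes. Total counts were 1523246, 1871041, 2159115, 2044677 and 1905918 for rAREG replicates 1 to 5, and 2023763, 1804171, 2118524 and 1868767 for vehicle replicates 1 to 4. Nothing in the labels says whether each library came from its own mouse, so p-values measure the spread between these libraries.

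The comparison asked how the TEC transcriptome differed 10 days after rAREG. Of 20 interferon response genes, 5 fell after rAREG and 15 did not pass. The list moved down (fry, adjusted p = 0.012) but did not pass camera with an estimated correlation (adjusted p = 0.078). Gbp2, an interferon-inducible GTPase, fell from 270 ± 4.42 CPM (UMI counts scaled to a common library total; SD, n = 4) in vehicle to 134 ± 15.3 (SD, n = 5), and Ifit1, an interferon-induced RNA-binding protein, from 495 ± 33.4 to 267 ± 42.2. Of 14 genes of the medullary stage that expresses Aire, the regulator of tissue-restricted antigens, 4 rose and 10 did not pass. The list moved up (fry, adjusted p = 0.012) but did not pass camera with an estimated correlation (adjusted p = 0.073). Aire itself rose from 729 ± 157 CPM (SD, n = 4) to 1159 ± 168 (SD, n = 5). Among 11636 genes tested with edgeR's quasi-likelihood test, 122 had an adjusted p under 0.05, of which 65 were higher and 57 lower in rAREG, while 1543 passed an unadjusted p of 0.05. The median fold was 1.60 among the genes that rose and 1.58 among those that fell, and 12 and 8 of them reached 2-fold. In 114 of the 122 the libraries of the groups did not overlap, against 4.92% of all genes tested and 1.59% by chance. The authors' deposited table, from their own fit, listed 168 genes with an adjusted p under 0.05, and 115 of the 122 were among them. The count depended on single libraries: it was 18, 43 and 230 without vehicle replicates 1, 2 and 4, and 58, 28 and 54 without rAREG replicates 1, 2 and 4. With DESeq2 in place of edgeR the count was 198, of which 120 were shared. With replicate numbers from the titles as a block it was 308, of which 117 were shared, and 43.8% of the 308 were higher in rAREG. With library numbers as a block it was 165, of which 97 were shared. With log2 library size as a covariate it was 92, of which 83 were shared. With a score of dissociation-response genes as a covariate, chosen after seeing the data, it was 36, of which 20 were shared. That score correlated with the group at −0.66, so the fit may also remove part of the group difference. Whether rAREG itself lowers these genes was not tested. A score of the TEC mix, also chosen after seeing the data, left 2 genes, none of them shared, and it separated the groups completely. In that fit Gbp2 was at −1.08 and Ifit1 at −0.83, without passing, and 22 of the 122 genes changed sign.

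**Figure D1:**
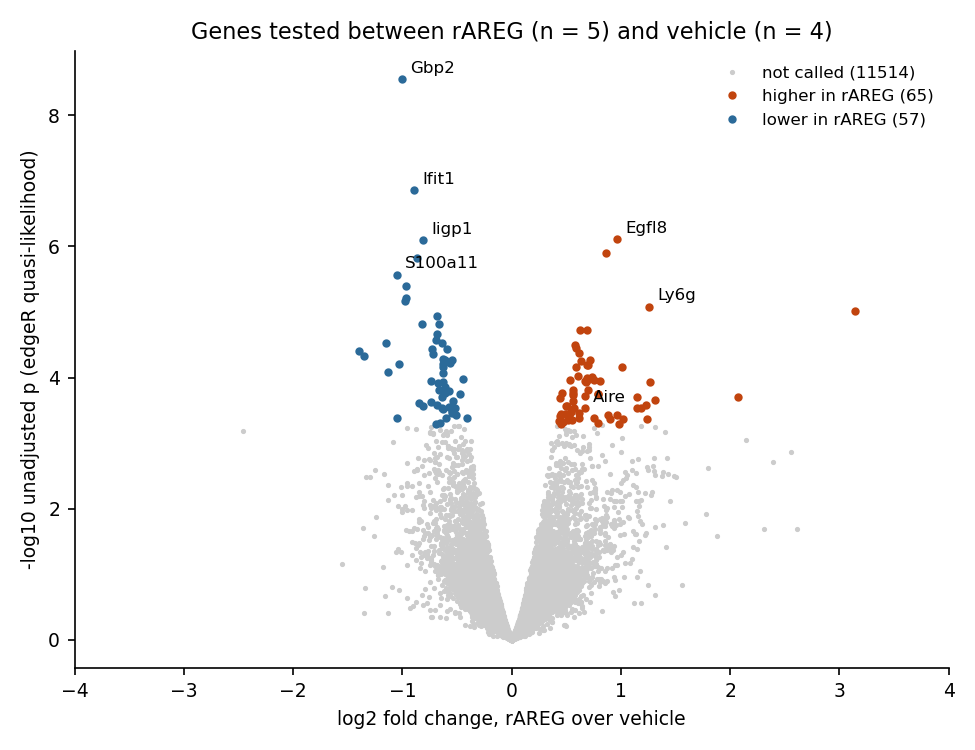
Each point is 1 of the 11636 genes tested, with the log2 fold change of rAREG (n = 5) over vehicle (n = 4) on the x axis and −log10 of the unadjusted p of edgeR's quasi-likelihood test on the y axis; 1 gene lies outside the plotted range of 4. The 65 genes that rose and the 57 that fell are coloured, and Gbp2 and Ifit1 have the smallest p.

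Among the genes that fell and that the naming rule allowed, the 10 with the smallest p were Gbp2, Ifit1, Iigp1, Ifit3, S100a11, Gstm2, Ifit3b, Ikzf4, Ccl2 and Nfkbiz. In log2 fold change ± SE, with edgeR's adjusted p, Gbp2 (chromosome 3, 142620602 to 142638008, GRCm38) fell by 1.01 ± 0.101 (adjusted p = 3.2e-05) and Ifit1 (chromosome 19, 34640871 to 34650009) by 0.89 ± 0.114 (adjusted p = 0.00081). Iigp1 (chromosome 18, 60376027 to 60392634), an immunity-related GTPase, was at −0.82 ± 0.117 (adjusted p = 0.0023), and Ifit3 (chromosome 19, 34583531 to 34588731) at −0.87 ± 0.129 (adjusted p = 0.0029). S100a11 (chromosome 3, 93520488 to 93526287), a calcium-binding protein, dropped by 1.05 ± 0.150 (adjusted p = 0.0045), from 313 ± 35.2 to 151 ± 37.5 CPM. The glutathione transferase gene Gstm2 was at −0.97 ± 0.150, Ifit3b at −0.97 ± 0.161 and Ikzf4, a zinc-finger transcription factor of the Ikaros family, at −0.97 ± 0.163, with adjusted p of 0.0058, 0.0079 and 0.0079. The chemokine gene Ccl2 (−0.69 ± 0.119) and Nfkbiz, an NF-κB cofactor (−0.82 ± 0.140), had adjusted p of 0.010 and 0.012. Each of these 10 passed in all 9 fits that left out 1 library, and with the dissociation score as a covariate Gbp2, Ifit1, Iigp1 and S100a11 did while the other 6 did not. Ifit3 and Ifit3b, close paralogs on chromosome 19, are uncertain as separate genes, since how reads matching both were counted is not given in the sources used here.

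Among the genes that rose and that the naming rule allowed, the 10 with the smallest p were Egfl8, Epsti1, Ly6g, Csn2, Fam89a, Lsp1, Calcb, H2-Eb2, Grin2c and Sema3b. Egfl8 (chromosome 17, 34613349 to 34615971), a secreted protein with EGF-like domains, rose from 34.5 ± 5.67 CPM (SD, n = 4) to 67.5 ± 6.21 (SD, n = 5), a log2 fold change of 0.96 ± 0.138 (SE; edgeR, adjusted p = 0.0023). Epsti1 (chromosome 14, 77904239 to 78002657) rose by 0.86 ± 0.127 (adjusted p = 0.0029). Ly6g (chromosome 15, 75155240 to 75159126), known as a surface marker of neutrophils, rose from 14.2 ± 4.88 to 34.3 ± 5.33 CPM (1.25 ± 0.213, adjusted p = 0.0088). The casein gene Csn2 was 1.62-fold higher, Fam89a 1.54-fold, the leukocyte actin-binding protein gene Lsp1 1.49-fold, the neuropeptide gene Calcb 1.51-fold, the class II gene H2-Eb2 1.53-fold, the glutamate receptor subunit gene Grin2c 1.64-fold and the semaphorin gene Sema3b 1.55-fold, with edgeR's adjusted p from 0.013 to 0.019. Egfl8, Epsti1 and Ly6g passed without any 1 library, and the other 7 lost their call without vehicle replicate 1; H2-Eb2 and Sema3b lost it also without vehicle replicate 2 or rAREG replicate 2, and Grin2c without vehicle replicate 3 or rAREG replicate 2. The largest adjusted p of these 7 in those fits was 0.079. With the dissociation score, Ly6g, H2-Eb2, Grin2c and Sema3b lost their calls.

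**Figure D2:**
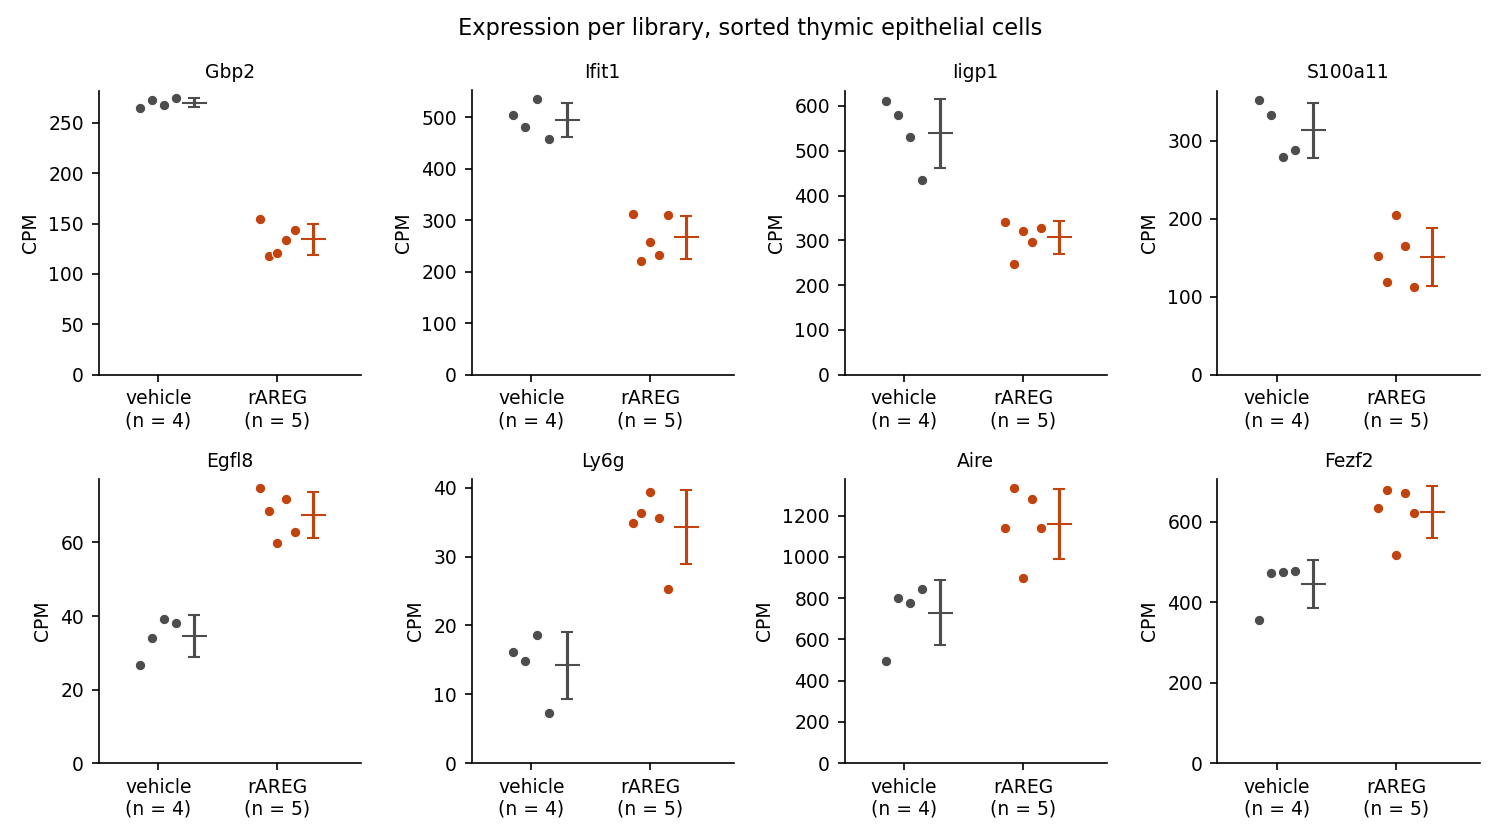
CPM of 8 genes (y axis, from 0) in each vehicle library (grey, n = 4) and each rAREG library (orange, n = 5); the bar beside each group is the mean ± SD. In the 4 upper panels every rAREG library lies below every vehicle library, and in the 4 lower panels it is higher than every vehicle library, with Aire at means of 729 and 1159 CPM.

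Of 28 gene lists fixed before the data were examined, 25 had at least 5 genes to test, and 3 moved one way by fry, limma's rotation test run on the edgeR fit. Among the 20 genes of the interferon response list, 5 fell, none rose and 15 did not pass over all genes tested, and 10 fell when adjusted over the list alone. Beside Gbp2, Ifit1 and Ifit3, the others that fell were the chemokine gene Cxcl10, from 4189 ± 605 to 2750 ± 493 CPM, and the transcription factor gene Irf1, from 909 ± 99.5 to 568 ± 141 CPM; both were named after their values were seen. Their log2 fold changes were −0.61 ± 0.131 and −0.68 ± 0.148 (SE; edgeR, adjusted p = 0.030 and 0.037). The median of the list was −0.33 and 17 of its 20 genes were negative (fry, adjusted p = 0.012). The list did not pass camera with an estimated correlation (adjusted p = 0.078). Its 3 positive genes, Cxcl9, Usp18 and Mx1, were at 0.21 ± 0.179, 0.016 ± 0.107 and 0.0045 ± 0.160 in log2 (SE) and did not pass. Irf7 and Oas2, at −0.093 ± 0.101 and −0.063 ± 0.229, did not pass either, so the fall was not shared by the whole list. The mean log2 CPM over the list was 7.09 ± 0.114 (SD, n = 5) in rAREG and 7.44 ± 0.0974 (SD, n = 4) in vehicle, with no overlap (two-sided exact permutation test, p = 0.0079, the smallest that 126 splits allow). Without vehicle replicate 3 the list's adjusted p by fry was 0.059, with the dissociation score as a covariate 0.070, and with the TEC mix score 0.86. The difference of the list score between the groups was −0.35 ± 0.072 (SE) with no covariate, −0.28 ± 0.094 with the dissociation score and −0.17 ± 0.185 with the TEC mix score. Cxcl10 passed only without vehicle replicate 2 or rAREG replicates 4 or 5, and Irf1 only without vehicle replicate 3 or rAREG replicate 5.

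In the list of Aire-stage medullary TEC, 4 of 14 tested genes rose, none fell and 10 did not pass over all genes tested, and 10 rose when adjusted over the list alone. Aire (chromosome 10, 78030022 to 78043610) rose by 0.67 ± 0.148 in log2 (SE; edgeR, adjusted p = 0.037). Fezf2 (chromosome 14, 12342094 to 12348189), another regulator of tissue-restricted antigens, rose from 445 ± 60.0 to 625 ± 65.0 CPM, and Relb (chromosome 7, 19606217 to 19629438), an NF-κB subunit needed for medullary TEC, from 202 ± 15.1 to 275 ± 27.6 CPM (adjusted p = 0.042 and 0.043). The fourth was the chemokine gene Ccl17, named after its values were seen, from 11.6 ± 3.01 to 27.2 ± 9.97 CPM (edgeR, adjusted p = 0.045). The list's median was 0.51, with 12 of 14 genes positive (fry, adjusted p = 0.012). The list did not pass camera with an estimated correlation (adjusted p = 0.073). Its score was 7.35 ± 0.0750 (SD, n = 5) in rAREG and 6.87 ± 0.152 (SD, n = 4) in vehicle (two-sided exact permutation test, p = 0.0079). The list passed without any 1 library, but with the dissociation score as a covariate its adjusted p was 0.065, and the TEC mix score, built in part from this list, removed its shift (median 0.041). The single genes were less secure: Aire, Fezf2 and Relb passed only in the fits without vehicle replicate 4 or rAREG replicate 3, with adjusted p up to 0.114, 0.195 and 0.188 in the other 7, and Ccl17 passed only without rAREG replicate 4. None of these 4 passed with log2 library size as a covariate, with adjusted p from 0.059 to 0.070. Of 10 tested dendritic cell genes in a list drawn up after seeing the data, 4 were higher when adjusted over the list alone, Fscn1, Cacnb3, Ly86 and Ccr7, and none passed over all genes.

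The list for medullary TEC that make CCL21 and keratins 5 and 14 moved down (fry, adjusted p = 0.036). The list did not pass camera with an estimated correlation (adjusted p = 0.24). Of its 14 tested genes, 2 fell, none rose and 12 did not pass over all genes tested, and 6 fell when adjusted over the list alone. The genes that fell were Ifitm3, an interferon-induced membrane protein, from 3064 ± 498 to 1977 ± 318 CPM, and Nrtn, the growth factor neurturin, from 199 ± 30.4 to 125 ± 23.2 CPM (edgeR, adjusted p = 0.022 and 0.024). Pdpn, for podoplanin, was at −0.64 ± 0.188 in log2 and passed over the list alone; without vehicle replicate 4 it passed over all genes (edgeR, adjusted p = 0.0088). Krt5 and Krt14, named after their values were seen, did not pass, with log2 fold changes of 0.10 ± 0.107 and 0.017 ± 0.105 (SE; edgeR, adjusted p = 0.74 and 0.97), and Ccl21a was not analysed here. Without Ifitm3 and Ly6a, which interferon induces, the median of the list went from −0.17 to −0.081, and that of its 4 keratins was 0.089. The list's call was lost without vehicle replicate 3 or rAREG replicates 1, 2, 3 or 5, with adjusted p of 0.090, 0.084, 0.063, 0.072 and 0.11. It was also lost with total-count scaling (0.062), upper-quartile factors (0.057) and limma voom (0.066), and with the dissociation score (0.070). With replicate numbers as a block, by title or by library number, the list did not pass either. Ifitm3 did not pass without vehicle replicate 1 or rAREG replicates 1 or 2, nor Nrtn without vehicle replicates 1 or 2 or rAREG replicates 1 or 2.

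**Figure D3:**
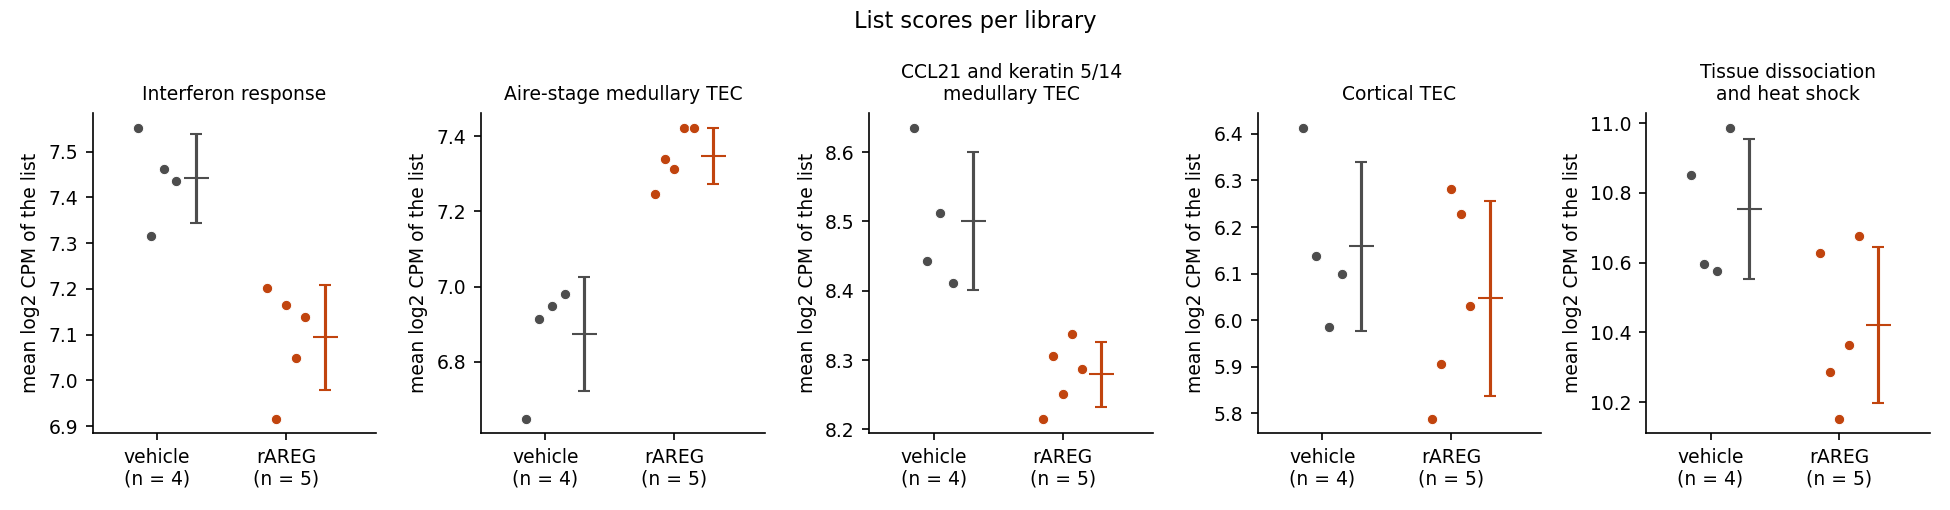
Mean log2 CPM over the genes of 5 lists (y axis, not starting at 0) in each vehicle library (grey, n = 4) and each rAREG library (orange, n = 5); the bar beside each group is the mean ± SD. The interferon response, Aire-stage and CCL21 and keratin 5/14 scores do not overlap between the groups, while the cortical and the dissociation scores do.

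The cortical TEC list did not pass (median −0.14, 11 of 16 genes negative; fry, adjusted p = 0.69), and Psmb11, the cortical proteasome subunit, was at 9.45 ± 3.07 CPM in rAREG (SD, n = 5) and 11.2 ± 3.68 in vehicle (SD, n = 4; edgeR, adjusted p = 0.79). Foxn1, the master regulator of TEC, was at 204 ± 43.9 and 158 ± 26.6 CPM (adjusted p = 0.28), and the cortical gene Tbata at 1806 ± 274 and 1617 ± 78.7. The progenitor list had a median of −0.046 (fry, adjusted p = 0.61), with Ly6d at 561 ± 130 and 559 ± 83.0 CPM. Ccl19, a chemokine that draws T cells into the medulla, was the only one of 14 thymopoietic factors to pass (0.71 ± 0.143 in log2; edgeR, adjusted p = 0.024), and the other 13 did not. It lost its call without vehicle replicates 1 or 2 or rAREG replicates 2 or 4. This list had no common direction (fry, adjusted p = 0.61), although fry's test for change in either direction passed (adjusted p = 0.0025).

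Lists of TEC that mimic other tissues did not move one way by fry. Tuft genes had a median of −0.091 (adjusted p = 0.75), with the ion channel gene Trpm5 at 68.9 ± 16.2 CPM in rAREG and 71.5 ± 12.4 in vehicle, and Lrmp at 152 ± 33.2 and 151 ± 43.4. Neuroendocrine genes went both ways: of 8, the transcription factor gene Insm1 rose 1.53-fold (edgeR, adjusted p = 0.044) and none fell (fry, adjusted p = 0.89; either direction, 0.035), while Resp18 was at −0.44 ± 0.135 and passed over the list alone. Insm1 passed only without vehicle replicate 4 or rAREG replicate 3. All 9 tested muscle genes were positive with a median of 1.11, and 5 passed when adjusted over the list alone but none over all genes (fry, adjusted p = 0.21; 0.022 without rAREG replicate 3). Among them Mymx was at 12.5 ± 4.15 CPM in rAREG and 5.53 ± 2.37 in vehicle, Ckm at 19.5 ± 9.58 and 8.93 ± 1.79, and Myh8 at 6.82 ± 1.89 and 2.81 ± 1.90. Without rAREG replicate 3, Mymx and Ckm passed over all genes (edgeR, adjusted p = 0.039 and 0.027), as Ckm did with a thymocyte score (0.044) or the dissociation score (0.016) as a covariate. All 9 microfold-like genes were also positive (median 0.22; adjusted p = 0.21), with Gjb2 at 151 ± 29.2 and 109 ± 19.6 CPM. Keratinocyte-like genes (median 0.12; adjusted p = 0.82), ciliated genes (median 0.20; 0.58) and intestine-, liver- and secretory-like genes (median 0.38; 0.60) did not pass. Their most abundant genes were Sbsn, Tppp3 and Wfdc2, at log2 fold changes of −0.24, −0.076 and −0.12.

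Genes of EGF receptor signalling did not pass as a group. Areg itself was at 18.3 ± 6.28 CPM in rAREG (SD, n = 5) and 10.8 ± 3.88 in vehicle (SD, n = 4; edgeR, adjusted p = 0.25), and Egfr at 36.8 ± 4.07 and 45.0 ± 6.03 (adjusted p = 0.37). The 7 tested genes of receptors and ligands had a median of −0.11 (fry, adjusted p = 0.61). Of 17 genes of ERK feedback and early response, 15 were negative, and Egr1, an immediate early transcription factor, fell 1.52-fold (edgeR, adjusted p = 0.044; fry for the list, adjusted p = 0.30). Fosl1 was at −0.77 ± 0.240 and passed over the list alone, and over all genes without rAREG replicate 5 (edgeR, adjusted p = 0.038). Egr1 passed only without rAREG replicates 1 or 5, and did not with total-count scaling (0.080) or limma voom (0.055). The S phase list (median 0.10; adjusted p = 0.73) and the G2 and M phase list (median 0.46, 15 of 16 genes positive; adjusted p = 0.43) did not pass. Mki67, a proliferation marker, was at 25.9 ± 6.58 and 22.7 ± 3.56 CPM, while Top2a and Birc5, at log2 fold changes of 0.46 ± 0.149 and 0.76 ± 0.248, passed over the list alone. Type 2 cytokine response genes went both ways, with a median of 0.014, a mean of −0.025 and a downward test (fry, adjusted p = 0.75; either direction, 0.043), and Arg2 was at 0.51 ± 0.145. Class II presentation genes had a median of 0.17 (adjusted p = 0.31), with H2-Oa at 0.45 ± 0.132, which passed without vehicle replicate 4 (edgeR, adjusted p = 0.038), and cholesterol synthesis genes a median of −0.16 (adjusted p = 0.13), with Hmgcs1 at −0.15 ± 0.183.

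The dissociation and heat shock list leaned the same way as the interferon list. Its score was 10.42 ± 0.224 in rAREG (SD, n = 5) and 10.75 ± 0.200 in vehicle (SD, n = 4; two-sided exact permutation test, p = 0.079; fry, adjusted p = 0.21), and 13 of 15 genes were negative. Atf3, Fosb and Fos, at −0.69 ± 0.174, −0.80 ± 0.209 and −0.49 ± 0.151, passed over the list alone but not over all genes with edgeR. Atf3 and Fosb passed with DESeq2 (adjusted p = 0.0085 and 0.0050) and with a thymocyte score as a covariate (0.0049 and 0.017). Fosb also passed with library size as a covariate (0.038). Without rAREG replicate 5, Atf3 and Fos passed with edgeR (0.0062 and 0.029), and without rAREG replicate 3 Fosb did (0.048). Markers of other cells did not pass by fry: thymocytes had a median of 0.033 but a mean of −0.0045 (adjusted p = 0.91), dendritic cells and macrophages 0.20 (0.31), fibroblasts −0.054 (0.75) and endothelium −0.27 (0.60). The most abundant or passing members were Coro1a at 0.41 ± 0.220 (edgeR, adjusted p = 0.46; 0.036 without vehicle replicate 4), Laptm5 at 0.45 ± 0.125 (edgeR, adjusted p = 0.091; DESeq2, 0.046), Gsn at −0.065 ± 0.101 and Plvap at 0.11 ± 0.184. Only 4 B cell genes and 1 erythroid gene were tested, too few for a list test, with Cd79b at 0.20 ± 0.149 and Alas2 at 0.029 ± 0.348, and mitochondrially encoded genes were not analysed here. Total counts, genes detected, and the shares of the 10 most abundant genes, of ribosomal protein genes and of the ribosomal RNA gene Rn45s did not pass a test between the groups (two-sided exact permutation tests, p from 0.071 to 0.76 over 5 measures; smallest adjusted p = 0.33).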

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

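The values of Myl6 and of the clock and kallikrein lists were examined only after the results were seen.

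A library far from the rest of its group, by Dixon's test at the 95% level, was found in 13 of 246 groups of values, where chance alone gives 12.3. For single genes, in CPM, vehicle replicate 1 stood apart for Fezf2 (355, others 473 to 477), Laptm5 (410, others 626 to 645) and Tbata (1735, others 1569 to 1586). Vehicle replicate 3 stood apart for Epsti1 (52.0, others 58.9 to 59.5) and Hmgcs1 (57.8, others 88.6 to 93.0), and vehicle replicate 4 for Fam89a (133, others 106 to 110) and Wfdc2 (896, others 720 to 723). Among rAREG libraries, replicate 1 stood apart for Gjb2 (203, others 131 to 147) and Egfr (43.9, others 33.7 to 35.9), and replicate 2 for Myl6 (342, others 499 to 524).

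For list scores in mean log2 CPM, vehicle replicate 4 was high for dendritic cells and macrophages (5.61, others 5.25 to 5.29). Vehicle replicate 3 was low for the circadian clock (4.88, others 5.29 to 5.33), and vehicle replicate 2 for the kallikrein 1b cluster (3.90, others 4.30 to 4.32). No explanation was tested for these single libraries, and their number is close to what chance gives.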

How the results depend on the processing

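The fits with a dissociation score or a TEC mix score as a covariate were chosen only after the results were seen, and so were 19 of the named genes; the other alternatives were planned. Unless a reason is given, the cause of a change was not tested.

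The 122 genes became 198 with DESeq2 (103 higher, 95 lower; 120 shared), 308 with replicate numbers from the titles as a block (135 higher, 173 lower; 117 shared) and 36 with the dissociation score (20 higher, 16 lower; 20 shared). A block by library number gave 165 genes (93 lower, 97 shared), and library size as a covariate 92 genes (41 higher, 83 shared). With RLE, upper-quartile or total-count scaling, no filter, a filter of 10 counts in 4 libraries (11752 genes tested), limma voom or a thymocyte score, the count was 119 to 152. Correlations of deviations between equally numbered libraries were 0.0745, 0.00253, 0.123 and 0.223 by title, the last 0.00749 by library number. Between libraries of unequal title number they ran from −0.217 to 0.135. The 0.223 was the highest of any pair, while the other values by title lay within the range of the unequal pairs. Whether replicate numbers pair the libraries is thus not settled, and neither the blocked nor the unblocked counts are preferred. Leaving out 1 library gave 18 to 230 genes, 5 to 117 higher and 13 to 113 lower. Fewest came without vehicle replicate 1 (18) and rAREG replicate 2 (28), most without vehicle replicate 4 (230). None of the 122 changed sign in any of these fits.

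The TEC mix score left 2 genes, 2 higher and 0 lower, none shared, and 22 of the 122 changed sign. The score is built from the Aire-stage and the CCL21 and keratin 5/14 lists, correlates with the group at 0.923 and separates the groups completely, so little of the group difference remains to be estimated beside it.

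Of the 3 lists that moved one way, 0 did with the dissociation score, the TEC mix score or camera with an estimated correlation. By the exact permutation test of list scores 0 passed either, but all 3 had the smallest p it allows (0.0079). That p becomes 0.066 after adjustment, so with 3 lists at it none could pass, however large the shift. Camera with a preset correlation called 9 lists. The CCL21 and keratin 5/14 list did not pass under either block (adjusted p = 0.22 by title, 0.25 by library number), while the dissociation and heat shock list passed under the block by library number (0.035). Leaving out 1 library gave 1 to 3 lists, with 1 list without vehicle replicate 3.

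Signs that changed, in log2 (medians for lists, where the direction is that of the test), were as follows. With the TEC mix score they were Grin2c −0.12, Ccl19 −0.14, Aire −0.24, Fezf2 −0.050, Insm1 −0.013, Laptm5 −0.35, H2-Oa −0.17, Pdpn 0.11, Ckm −0.0025, Myh8 −0.39, Egfr 0.15, Coro1a −0.61, Cd79b −0.23, Sbsn 0.083, Psmb11 0.73, Tppp3 0.21, Gsn 0.022, Alas2 −2.07, Lrmp −0.86, Ly6d −0.072, Gh −0.35. For lists they were cortical TEC 0.45, CCL21-producing and keratin 5/14 medullary TEC 0.026, Aire-stage medullary TEC 0.041, intestine-and-liver-like and secretory −0.17, S phase −0.13, G2 and M phase −0.92, MHC class II presentation −0.22, thymocyte −0.55, dendritic cell and macrophage −0.36, fibroblast 0.28, endothelial 0.098. With the dissociation score they were Sbsn 0.036, Mki67 −0.20, Hmgcs1 0.21, Tppp3 0.035, Gsn 0.035, Trpm5 0.094, Krt14 −0.035. The lists were candidate TEC progenitor −0.014, tuft 0.083, S phase −0.13, thymopoietic factors 0.0078. With library size they were Lrmp −0.039, Ly6d −0.042, and for lists keratinocyte-like −0.015, thymocyte 0.039. With no filter it was Ly6d −0.00082. With a block by library number they were Trpm5 0.094, Alas2 −0.090, Krt14 −0.019, and for lists tuft 0.066, type 2 cytokine and IL-4/IL-13 response 0.0088. With a block by title number they were Alas2 −0.13, Lrmp −0.051, and for lists neuroendocrine −0.15, thymocyte −0.051. With total counts it was neuroendocrine −0.16. Over the fits that left out 1 library, the ranges were Alas2 −0.22 to 0.28, Krt14 −0.022 to 0.082, Lrmp −0.11 to 0.19, Ly6d −0.13 to 0.12, Psmb11 −0.33 to 0.034, Trpm5 −0.13 to 0.093, Wfdc2 −0.30 to 0.029. Those of lists were fibroblast −0.21 to −0.040, keratinocyte-like −0.12 to 0.17, neuroendocrine −0.28 to −0.014, thymocyte −0.051 to 0.17, tuft −0.18 to 0.054, type 2 cytokine and IL-4/IL-13 response −0.14 to −0.0097.

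The 45 named genes that passed were refitted under each alternative fixed before the data were examined, where a call was kept 477 times and lost 18 times. The losses fell on 12 genes. Library size as a covariate accounted for 8 of them, the block by library number for 5 and limma voom for 3. Total-count scaling and the block by title number accounted for 1 each. With each library left out, a call was kept 269 times and lost 136 times. No sign changed in either. On counts simulated at this depth and number of libraries, 14.5% of 1.5-fold changes were recovered; which of the 2 limits this more was not tested. Genes that had not passed did so 16 times under these alternatives and 9 times with a library left out. Under the block by title number these were Atf3, Fosb, Fos, Fosl1, Laptm5 and H2-Oa (adjusted p = 0.00016, 0.00016, 0.0023, 0.021, 0.027 and 0.034), and under the block by library number Atf3, Fosb and Fos (0.026, 0.000975 and 0.039).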

Other observations

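Tests of the 10 further lists, of fewer macrophages and dendritic cells, and of fewer cortical TEC were chosen only after the results were seen, as were the fits with dissociation and TEC mix scores and the requirement that a bound be passed by more than its spread.

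Of the 10 further lists, 9 had enough genes to test and 4 moved one way by fry, adjusted over these 9. Since these lists were drawn up from the genes that changed, their p-values are not independent evidence. Values given with an estimated correlation are those of camera, adjusted over the same 9 lists. Interferon-inducible GTPases and related genes fell in 7 of 17 genes, with 16 negative and a median of −0.55 (adjusted p = 0.00093; 0.010 with an estimated correlation); Irgm1 was at −0.72 and Rtp4 at −0.66. Peptide hormones and neuropeptides rose in 5 of 25, Calcb, Cga, Nts, Adipoq and Gh, with 21 positive and a median of 0.61 (adjusted p = 0.010; 0.033 with an estimated correlation), and Cga went from 20.4 to 40.9 CPM. NF-κB early genes fell in 5 of 13, among them Ccl2, Nfkbiz, Tnfaip3 (−0.73) and Cd274 (−0.63), with 11 negative and a median of −0.26. Their adjusted p was 0.015 by fry and 0.072 by camera with an estimated correlation. The 2 positive genes were Cxcl2 (0.46), which passed over the list alone, and Nfkbia (0.068). SRF and YAP targets and actomyosin genes fell in 5 of 21, among them Myl6 (−0.68), Lmna (−0.44) and Srf (−0.54), with 18 negative and a median of −0.23. Their adjusted p was 0.027 by fry and 0.14 by camera with an estimated correlation. Of the 3 positive genes, Tpm2 (0.41) passed over the list alone. The circadian clock list did not pass (median −0.36; adjusted p = 0.062), with Dbp at −0.74, nor did the kallikrein 1b cluster (median 0.17; 0.27) or the neutrophil list (median −0.18 with an upward test; 0.44). Of these genes, Cga, Nts, Adipoq, Gh, Lmna, Srf and Dbp lost their calls without vehicle replicate 1, without vehicle replicate 2 and without rAREG replicate 2, with adjusted p up to 0.195; in other fits that left out 1 library some of them did too. Irgm1, Rtp4, Tnfaip3 and Myl6 lost theirs without vehicle replicate 1 (0.051 to 0.076), Irgm1 and Tnfaip3 also without rAREG replicate 4 (0.060 and 0.051), and Tnfaip3 without vehicle replicate 2 (0.066). Cd274 lost its call without vehicle replicate 3 or rAREG replicate 2 (0.059 and 0.072).

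Chance as the source of the counts was tested on 100 of the 126 splits of the 9 libraries. The 122 changed genes were reached by 1 split, the real one, with 114 the highest other. For the 65 higher genes it was also 1 (highest other 41), for the 57 lower genes 2 (highest other 73), and for the 3 lists 1 (highest other 1). For each, fewer than 5% of the 100 splits run reached the real result. For the lower genes another split called more than the real grouping, and the splits not run could change that share. The split with 114 genes exchanged rAREG replicate 3 and vehicle replicate 4, which lie between the groups on the first principal component (0.323 and 1.62, against 6.93 to 16.2 for the other rAREG and −23.8 to −9.01 for the other vehicle libraries).

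Of 20 interferon response genes, 5 fell after rAREG and 15 did not pass. The list moved down by fry but did not pass camera with an estimated correlation (adjusted p = 0.078). Fewer macrophages and dendritic cells in the rAREG sorts are argued against as the whole cause: their list had a positive median (0.20; Cst3, Laptm5 and Lyz2 at 1538, 578 and 260 CPM in vehicle, Tyrobp at −0.29 ± 0.235 and Fcer1g at −0.27 ± 0.283), and its score moved apart from that of the interferon list (two-sided exact permutation test, p = 0.016), also without Cst3, Laptm5 and Lyz2, which TEC may express (0.024). A stronger dissociation response in the vehicle libraries stays open: with its score as a covariate the median was −0.23, past the bound of −0.2 set beforehand but by less than the standard error of the score difference, which went from −0.35 ± 0.072 to −0.28 ± 0.094, while the second condition set beforehand, an unadjusted fry p under 0.05, was met (0.014; adjusted over the lists, 0.070 against 0.012 without the covariate). A shift of the TEC mix cannot be told apart from a change within cells, because the mix score follows the groups: with it the median was −0.17 (fry, adjusted p = 0.86; score difference −0.17 ± 0.185), while Gbp2 (−1.08) and Ifit1 (−0.83) were about as large as without it, and neither passed. An effect of rAREG on the cells themselves remains as an untested hypothesis.

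Of 14 Aire-stage genes, 4 rose after rAREG and 10 did not pass. The list moved up by fry but did not pass camera with an estimated correlation (adjusted p = 0.073). Fewer cortical TEC in the rAREG sorts would lower the cortical list and raise every medullary list. The cortical list leaned down without passing (median −0.14, 11 of 16 genes negative, fry, adjusted p = 0.69). However, the CCL21 and keratin 5/14 list had a median of −0.17 (fry, adjusted p = 0.036). It did not pass camera with an estimated correlation (adjusted p = 0.24). Its median was −0.081 without the interferon-induced Ifitm3 and Ly6a, and its 4 keratins were slightly positive, such as Krt5 (0.10) and Krt17 (0.13). The fry call was lost without vehicle replicate 3 (0.090) and rAREG replicates 1, 2, 3 and 5 (0.084, 0.063, 0.072 and 0.11). It was also lost with replicate numbers as a block, by title or by library number. The list's score moved apart from the Aire-stage score with the keratins alone (two-sided exact permutation test, p = 0.016). It also did without Ifitm3 and Ly6a (two-sided exact permutation test, p = 0.0079, the smallest possible). However, the Aire-stage score alone also reached the smallest possible p, so a nearly flat list could move apart from it too. Score differences were 0.096 for the keratins, −0.17 without Ifitm3 and Ly6a and 0.47 for the Aire-stage list. An equal rise of all medullary genes was thus not seen. These tests cannot decide on fewer cortical TEC, which stay open. More dendritic cells in the rAREG sorts stay open. A list of 10 tested genes, meant to leave out those shared with TEC, had a median of 0.23, between the bounds set beforehand. Ptprc was at 9.75 CPM in vehicle, far below Fscn1 and Cacnb3, and whether TEC express these was not tested. The list's score did not move apart from the Aire-stage score (two-sided exact permutation test, p = 0.15). In either direction its adjusted p by fry was 0.00068. The list was drawn up after the results were seen, so that p is not independent evidence. Its most abundant genes Fscn1 (0.53; 122 CPM in vehicle) and Cacnb3 (0.38; 96.9 CPM), with Ly86 (1.11) and Ccr7 (0.63), passed over the list alone, while Ptprc (−0.48), Itgb2 (−0.38) and Tyrobp (−0.29) were negative and did not, and the sort for TEC was meant to remove such cells.

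Some genes known from leukocytes rose, such as Ly6g, Lsp1, Ncf1 (0.57) and Ncf4 (0.59); 10 such genes were picked from those that rose, with no test of their share, and their median of 0.77 is high by that choice. More leukocytes in the rAREG sorts stay open: the 14 tested pan-leukocyte genes, 7 positive and 7 negative, had a median of −0.00061 whose 95% bootstrap interval over members, −0.27 to 0.41, reaches past the bounds set beforehand (mean 0.058; fry, adjusted p = 0.48; either direction, 0.016). The median itself met the bound set beforehand. The demand that its interval meet it too was made after the results were seen. The other condition set beforehand, that 0.77 exceed the interval, was also met, but that value is high by choice. Among the list's most abundant genes, Srgn (1900 CPM in vehicle, 2523 in rAREG) and Laptm5, which TEC may express (578 and 787), did not overlap between the groups. Both passed over the list alone (edgeR, adjusted p = 0.015), while Cd52 was at 424 and 431. Ptprc (−0.48), Itgb2 (−0.38), Tyrobp (−0.29) and Fcer1g (−0.27) leaned down and did not pass. The neutrophil list had a median of −0.18, with Ly6g at 1.25 but Il1b at −1.04 and S100a9 at −0.75. Ncf1 lost its call without vehicle replicates 1, 2 or 3 or rAREG replicates 1, 2 or 4 (adjusted p up to 0.17) and Ncf4 without vehicle replicates 1 or 3 or rAREG replicates 1 or 4 (up to 0.093).

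Some genes were spread unevenly within a group. Mir692-1 had 855, 1451 and 1516 counts in rAREG replicates 1, 4 and 5 and 7 to 14 in the other libraries. Gm2381 had 69 counts in vehicle replicate 2 and 0 in the others.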
